A study of Arabidopsis thaliana with 44 samples.

How the data were processed

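Shoots of 3-week-old Arabidopsis thaliana plants grown in soil with 16 h of light were compared between WT and the mutants pkl-1, clf-28 and pie1-5. The labels list 44 samples. RNA-seq has 12, anti-H3K27me3 and anti-H2A.Z chromatin immunoprecipitations (ChIP) have 8 each, and anti-H3 immunoprecipitations and input DNA have 8 each. The series design text calls the 3 RNA-seq and 2 ChIP-seq libraries of a genotype independent biological replicates. Anti-H3 and input libraries were not analysed here, so no value below is relative to input or to H3 density.

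Per the submitters' processing notes, Trimmomatic, Bowtie2, edgeR, SICER, bedtools and deepTools were used with the build TAIR10. Their versions, their settings and the read counter are not given in the sources used here. The authors deposited a table of raw read counts per gene for the 12 RNA-seq libraries. They also deposited a table of log2 fold changes with p-values and adjusted p-values for each mutant against WT. For each ChIP replicate, the authors deposited 1 table of regions that sets 1 mutant library against WT. Per the file headers it gives read counts, RPM (reads scaled to the library total), the ratio of the RPM values and 1-sided p-values with an FDR. Region boundaries lie on 200 bp windows, and coordinates are given 1-based in TAIR10. Library totals of the ChIP libraries were recovered from the deposited counts and RPM. RPM divides by all reads of a library, so more background reads in an immunoprecipitation lower the RPM of its enriched regions. Background reads also fall inside regions, so the regions need not be lowered by the same factor. The cDNA kit named in the labels does not mark strand, so reads of overlapping genes cannot be told apart. Intervals and floors cover counting error only, because reads were summed over the libraries of a group, which leaves out the spread between libraries. The reads carry no molecular identifiers, so copies of 1 molecule cannot be told apart.

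Gene names came from a RefSeq gene table of the assembly TAIR10.1, used for names and for placing genes in regions. None of its coordinates are printed. As a check of that placing, 28 of 30 genes of the floral and meristem lists named below lay in H3K27me3 regions of pkl-1 replicate 2, against 2 and 6 after shifting the genes by 20 kb either way.

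Gene counts were tested with edgeR 4.0.16 in R 4.3.3. TMM factors, the default filter on low counts, 1 common fit of all 12 libraries and the quasi-likelihood F test were used. Adjusted p-values are Benjamini-Hochberg values over the 20375 genes tested, and genes below 0.05 were called changed. CPM are counts scaled by library size and TMM factor, given as mean ± SD of 3 libraries. Fold changes are edgeR estimates, with a standard error (SE) derived from the F statistic. Where a group held 0 counts, the fold was set against a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio of counts is given with its 95% counting interval.

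The following 20 lists, with 279 genes in all, were examined. They were targeted genes, Polycomb and H3K27me3 machinery, SWR1, H2A.Z and CHD remodelers, floral MADS-box and floral identity, flowering time, embryo and seed storage, and meristem and leaf polarity. Others were gibberellin metabolism and signalling, salicylic acid defence, jasmonate response, heat shock, cold and dehydration response, phosphate starvation, circadian clock and photosynthesis. The rest were flavonoid and anthocyanin, PIF and brassinosteroid elongation, leaf senescence, and markers of root and of anther and pollen as other tissues. Each list except that of anther and pollen, which had 2 tested members, was compared with all other genes by camera in limma 3.58.1 with the preset correlation of 0.01, adjusted over all lists and mutants, and again with the correlation estimated from the data.

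The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the targeted genes and, per mutant, the 8 largest rises and 8 largest falls. Those genes had to be called, to have a mean log2 CPM of at least 1 and to separate every mutant library from every WT library. It also names up to 4 called members per list and mutant with the smallest adjusted p, and FLC, AG, SEP3, STM, FT and LEC1 whatever their result. For genes called alike in all 3 mutants it names the 5 in each direction whose largest adjusted p was smallest. Per mark and mutant it names the 3 largest rises and falls of regions with at least 100 reads in the mutant or the WT library in both replicates, and the regions over those 6 genes.

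ChIP regions of the 2 replicate tables were paired as best matches both ways that overlapped by at least 50% of the shorter region. Their counts were tested with edgeR's quasi-likelihood test with the recovered library totals and Benjamini-Hochberg adjustment. The length of a region in its replicate table was an offset in every such fit, with and without the block. The H2A.Z tables hold 2 WT libraries, and replicate number was a block as planned. All 6 H3K27me3 tables hold identical WT counts wherever their regions have the same coordinates, so they hold 1 set of WT counts. The headers name no WT replicate, so these may come from 1 library or from the 2 pooled. They were treated as 1 WT library and are called so below. The planned block could not be fitted there, and 2 mutant libraries were tested against 1 WT library, whose spread is assumed to equal that of the mutant libraries. A gene was placed in a region that covered at least 50% of its length. Enrichment of called genes in regions was tested with Fisher's exact test, with the tested genes that could be placed as background.

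Overlaps between mutants share the WT libraries, so 20 simulations of unchanged genotypes against shared WT libraries were run. They show what shared WT libraries give where no gene changed, not how far they add to overlaps among changed genes. Alternatives were RLE size factors, no filter on low counts, a fold change of at least 2 (1 on the log2 scale), only the 2 genotypes compared, DESeq2 1.42.0, replicate number as a block, and leaving out each library. For ChIP they were TMM over the matched regions, an overlap of at least 80% of the longer region, an adjusted p below 0.01, the deposited FDR in both replicates, no block, and any overlap with a gene. Definitions from the deposited FDR together with a 1.5-fold difference, and some settings for shared counts, were added after the counts of called regions had been seen.

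On simulated counts with 200 of 19493 genes changed in pkl-1 against WT, the gene test recovered 14.9% of 2-fold and 73.5% of 4-fold changes and called 0.0311% of unchanged genes. In the H3K27me3 simulation 41% of 2-fold and 100% of 4-fold changes were recovered in pkl-1 over 5337 regions. The recovered shares were 0% and 0% in clf-28 over 5441 regions, and 5% and 28% in pie1-5 over 5180 regions. For H2A.Z they were 100% and 100% in pkl-1 over 9861 regions, 62% and 100% in clf-28 over 14539, and 7% and 82% in pie1-5 over 14570. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.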

Results

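Transcript levels, H3K27me3 and H2A.Z in Arabidopsis shoots were compared between WT and mutants of 3 chromatin genes, pkl-1, clf-28 and pie1-5. PKL is a CHD3-type chromatin remodeler, CLF a Polycomb methyltransferase of histone H3 lysine 27, and PIE1 the ATPase of the SWR1 complex that places the histone variant H2A.Z. RNA-seq gave 3 libraries per genotype, 12 in all. Reads over 33341 genes numbered 26.5, 31.3 and 24.9 M in WT and 28.1, 33.1 and 27.2 M in pkl-1. They numbered 28.6, 21.6 and 31.3 M in clf-28 and 32.2, 30.5 and 26.1 M in pie1-5. Reads fell on 25807 genes in pkl-1 2 and on 21380 (WT 1) to 22847 (pie1-5 1) in the other libraries, and the cause was not tested. Plastid genes took 30.8% to 39.7% of the reads of a library. Mitochondrial genes took 6.70% to 7.09% in pie1-5 and 5.18% to 5.86% in WT. Across genes, which are not independent replicates, each library correlated best with a library of its own genotype. The first principal component (25.8% of the variance) placed the pie1-5 libraries between 68.4 and 85.7 and every other library at 0.853 or below. H3K27me3 libraries held 13.6 M reads in WT, 19.2 and 10.9 M in pkl-1, 6.44 and 3.17 M in clf-28, and 16.0 and 13.9 M in pie1-5. H2A.Z libraries held 19.1 and 19.3 M reads in WT, 14.8 and 12.9 M in pkl-1, 10.7 and 7.62 M in clf-28, and 8.22 and 10.3 M in pie1-5.

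The mutated genes were examined first. PKL (AT2G25170) stood at 17.7, 15.2 and 17.7 CPM in the WT libraries and at 29.0, 29.3 and 35.2 CPM in the libraries labelled pkl-1. This is 1.85-fold higher (log2 fold change 0.89 ± 0.21 SE, n = 3, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0247). CLF (AT2G23380) stood at 3.04, 5.99 and 2.72 CPM in WT and at 23.6, 22.8 and 34.2 CPM in the libraries labelled clf-28, 6.81-fold higher (2.77 ± 0.28, adjusted p = 7.99e-05). PIE1 (AT3G12810) stood at 8.10, 6.86 and 10.1 CPM in WT and at 3.73, 3.95 and 5.69 CPM in pie1-5. It was 1.87-fold lower and below every WT library in 3 of 3 libraries, but it missed the threshold in the edgeR test (−0.90 ± 0.27, adjusted p = 0.0565; DESeq2 0.0342). PKL measured 21.1, 19.3 and 30.9 CPM in clf-28 and 17.2, 13.5 and 21.5 CPM in pie1-5. CLF measured 4.24, 3.83 and 4.92 CPM in pkl-1 and 4.73, 5.25 and 4.91 CPM in pie1-5. PIE1 measured 10.9, 10.1 and 10.9 CPM in pkl-1 and 9.19, 9.74 and 18.7 CPM in clf-28. None of these 6 differences from WT passed the threshold. The PKL call was lost when any of the 6 libraries was left out (WT 1, 2 or 3, or pkl-1 1, 2 or 3; adjusted p up to 0.110). Transcripts of PKL and CLF were not reduced in the libraries that carry their labels, so the counts do not check those labels. All 3 genes overlap other annotated genes. As a list, the targeted genes were called higher in clf-28 (camera adjusted p = 4.24e-06, median 0.60, and 0.27 without clf-28 3), with 3 of 3 higher when adjusted over the list alone and 1 over all genes. That call was lost at adjusted p = 0.0828 with an estimated correlation. The list holds CLF itself, the 1 member called over all genes, so its call is not separate from the CLF value above. The list was not called in pkl-1 (adjusted p = 0.106, 1 higher both ways of counting). In pie1-5 it was not called either (0.680, none over all genes, 1 lower adjusted over the list alone), and its median (0.05, from −0.13 without pie1-5 3 to 0.20 without pie1-5 2) is positive while mean (−0.18) and test point down.

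**Figure D1:**
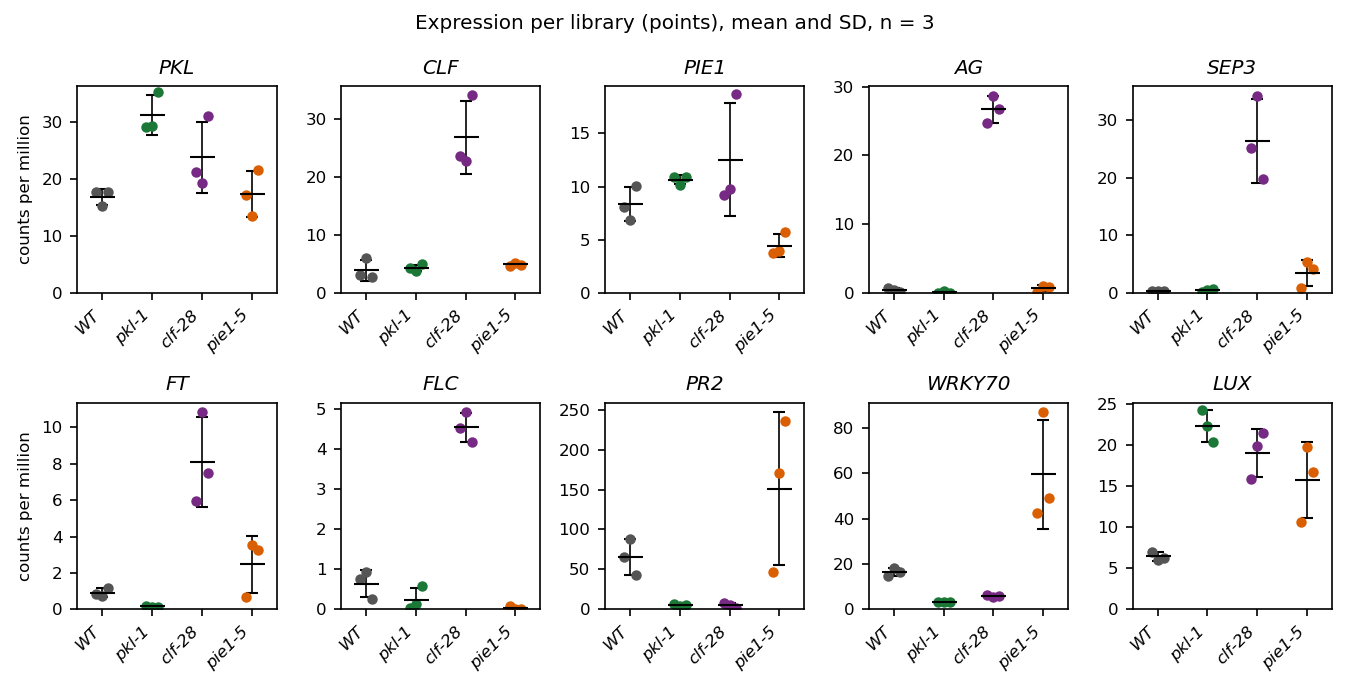
CPM of PKL, CLF, PIE1, AG, SEP3, FT, FLC, PR2, WRKY70 and LUX in each of the 12 RNA-seq libraries (points), with mean and SD of the 3 libraries of a genotype. CLF averages 26.9 CPM in the libraries labelled clf-28 against 3.92 CPM in WT, and WRKY70 averages 3.47 CPM in pkl-1, 59.5 CPM in pie1-5 and 16.6 CPM in WT.

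In the libraries labelled pkl-1, PHE1, a MADS-box gene imprinted in endosperm, rose from 0.209 ± 0.201 to 38.6 ± 3.46 CPM, 167-fold (log2 fold change 7.38 ± 0.66 SE, adjusted p = 1.05e-05). Of 21 salicylic acid defence genes 9 fell, a list called by camera with its preset correlation (adjusted p = 4.24e-14) and not with an estimated one (0.0828). Among them PR2, a glucanase gene induced by pathogens, went from 66.1 ± 22.5 to 5.47 ± 1.35 CPM, 12.1-fold lower (−3.60 ± 0.55, adjusted p = 0.00143). AT5G42530, among the abundant transcripts of WT, went from 3257 ± 289.8 to 91.4 ± 21.4 CPM, 35.6-fold lower (−5.15 ± 0.46, adjusted p = 1.05e-05). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 295 genes were higher and 526 lower than in WT, 821 of 20375 tested. Without 1 library the total was 412 (WT 3), 414 (pkl-1 1), 476 (pkl-1 2) and 461 (pkl-1 3), and DESeq2 called 1401. The authors' deposited table lists 488 genes higher and 734 lower at its adjusted p below 0.05.

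Other large rises in pkl-1 were AT4G02825 (8.90 ± 1.45 to 207 ± 19.5 CPM, 23.2-fold, adjusted p = 1.70e-09), AT4G02795 (30.1-fold, 1.19e-04), FKF1, a blue-light receptor gene of the photoperiod pathway (28.9-fold, 0.00707), and AT4G33980 (22.9-fold, 0.00743). COR27, a cold-regulated gene of the clock, rose 50.3-fold (0.0221), a call lost without WT 1, WT 2, WT 3 or pkl-1 3 (up to 0.0992). Whether another collection time of WT, raised below for clock genes, also moved FKF1, AT4G33980 and COR27 was not tested. AT3G01345 and AT1G75945 had no read in WT. AT3G01345 was at least 554-fold higher (20.5 ± 16.8 CPM, adjusted p = 0.00164) and AT1G75945 at least 42.7-fold higher (1.77 ± 1.46 CPM). Without WT 2 these bounds were 344 and 26.6, and without pkl-1 1 that of AT1G75945 was 28.8. The largest falls were PCR1 (81.7-fold, 2.93e-04), the receptor-like protein gene RLP23 (56.4-fold, 5.30e-06), the chaperone gene BIP3 (27.9-fold, 5.86e-04) and ANK (26.2-fold, 5.37e-05). AT5G06570 was 25.7-fold lower (0.00166) and AT5G59670 22.6-fold lower (1.38e-04). AT5G26690 kept 2 reads in pkl-1, a ratio of 76.9 (95% counting interval 20.9 to 641). Both reads lie in pkl-1 2, and without it the gene was at least 32.1-fold lower. RLP23 overlaps VAMP725, ANK overlaps RPL24, FKF1 overlaps MAP70-1, AT4G02795 overlaps AT4G01980 and AT5G26690 overlaps AT5G26680, so reads of each pair cannot be told apart. Without 1 library some folds moved by more than 1.5 times. FKF1 was 58.2-fold higher and AT5G06570 14.2-fold lower without WT 3, and PHE1 309-fold and AT4G33980 46.7-fold higher without WT 2. BIP3 was at −4.14 on the log2 scale without pkl-1 2 and at −6.58 without pkl-1 3, and AT5G59670 50.8-fold lower without pkl-1 2. PCR1 had reads in pkl-1 2 alone among the pkl-1 libraries, the RNA-seq library with reads over the most genes (25807).

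Of 21 salicylic acid defence genes, 9 fell and none rose in pkl-1, and 14 fell when adjusted over the list alone. WRKY70 was 4.77-fold lower (adjusted p = 5.97e-05), PR5 7.85-fold (2.93e-04) and PR1 8.47-fold (0.00430; 20.9-fold without pkl-1 2). FMO1, WRKY38 and ALD1 had no read in pkl-1 and lay at least 15.3-, 5.34- and 5.34-fold lower, without passing the threshold. WT 3 held no read of these 3 genes either. Without WT 2 the bounds of FMO1 and WRKY38 were 3.44 and 1.72, without WT 1 that of ALD1 was 2.62, and without pkl-1 2 they were 9.58, 3.34 and 3.34. The list median was −1.64 on the log2 scale, also with those 3 genes at their bounds (camera adjusted p = 4.24e-14, but adjusted p = 0.0828 with an estimated correlation). In the circadian clock list 3 of 11 rose (5 higher and 1 lower adjusted over the list alone). LUX rose 3.46-fold (2.21e-04), GI 3.03-fold (0.00489) and ELF4 from 3 to 112 reads, a ratio of 34.9 (95% counting interval 11.7 to 172; 0.0288; ratio 73.2 without WT 3). The list was called higher (0.00849; adjusted p = 0.117 with an estimated correlation). WT collected at another time of day than pkl-1, raised below, may explain these clock values, and an effect of the mutation stays open. The flavonoid and anthocyanin list was called higher (2.29e-04; adjusted p = 0.288 with an estimated correlation), with 2 of 13 higher (3 adjusted over the list alone). These were DFR, 3.53-fold (0.0159), and LDOX, 4.01-fold (0.0248), both enzymes of anthocyanin synthesis. The embryo and seed storage list was called higher (0.0185; adjusted p = 0.158 with an estimated correlation), with PHE1 as its only called member of 5 in either count. LUX overlaps AT3G46650. The ELF4 call was lost without any 1 of the 6 libraries (WT 1 to 3, pkl-1 1 to 3; up to 0.102), DFR without WT 1, WT 3 or pkl-1 1 (0.0740), and LDOX without WT 1, WT 3, pkl-1 1 or pkl-1 3 (0.104). Without WT 2, DFR was 6.61-fold and LDOX 6.39-fold higher, and the median of the flavonoid list was 1.46 against 0.78, and 0.52 without WT 1. Without WT 2 that of the embryo list was 2.42, without WT 3 1.32 and without pkl-1 1, 2 and 3 0.91, 0.89 and 1.16, against 0.57.

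The floral MADS-box and floral identity list was called lower in pkl-1 (camera adjusted p = 0.0266; adjusted p = 0.288 with an estimated correlation), with a median of −0.61, and −1.02 without pkl-1 2. AGL24 was its 1 called member of 11 in both counts (2.55-fold lower, 0.0320). AG (−1.60 ± 0.87, adjusted p = 0.372), SEP3 (0.47 ± 0.65, 0.779), FLC (−1.39 ± 0.74, 0.361) and STM (−0.87 ± 0.44, 0.329) were not called, and LEC1 was not among the tested genes. In the flowering time list (camera adjusted p = 0.418) 2 of 17 fell (1 higher and 3 lower adjusted over the list alone). They were SPL5 (72 to 3 reads, ratio 25.6, 95% counting interval 8.43 to 127; adjusted p = 0.00218; ratio 48.1 without pkl-1 2) and the florigen gene FT (0.920 ± 0.243 to 0.162 ± 0.0128 CPM, 5.52-fold, 0.0324). Of 12 cold and dehydration genes 3 fell (4 adjusted over the list alone; camera adjusted p = 0.160), ERD10 (2.39-fold), RAB18 (2.18-fold) and RD29A (2.85-fold). WT 3 carries much of the ERD10 and RD29A folds, and without it ERD10 was 1.58-fold and RD29A 1.44-fold lower, neither called. The list median of −0.67 was then −0.16, and −0.44 and −0.32 without pkl-1 2 and 3. The jasmonate response list had 1 member higher, PDF1.2A (2.53-fold, and 4.34-fold without WT 2), and 3 lower, JAZ1 (3.05-fold), JAZ5 (3.40-fold) and MYC2 (1.94-fold). In pkl-1 1, JAZ5 (10.9 CPM) and MYC2 (39.8 CPM) were not below WT 1 (10.4 and 36.8 CPM). Adjusted over the list alone these were 4 and 6 (camera adjusted p = 0.538). SEN1, a senescence-associated gene, fell 5.26-fold (0.0128; 1 of 6 senescence genes in both counts, camera adjusted p = 0.175). GA2OX2 fell 2.85-fold (0.0189; 1 of 17 gibberellin genes, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.708). The root marker PYK10 rose from 27.4 ± 7.06 to 53.3 ± 2.64 CPM (1.94-fold, 0.00987; 1 of 3 root markers in both counts, camera adjusted p = 0.160).

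Among chromatin genes in pkl-1, the Polycomb gene RING1B rose 2.37-fold (adjusted p = 0.0383; 1 of 20 list members, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.987). That list has a median of −0.01 (−0.05 without WT 2 to 0.02 without pkl-1 3) and a mean of 0.07. PKR1, a CHD3 paralog of PKL, fell 1.69-fold (0.0300; 1 of 10 SWR1, H2A.Z and CHD genes in both counts, camera adjusted p = 0.597). No member was called in 5 lists. These were heat shock (8 tested, camera adjusted p = 0.313), photosynthesis (16, 0.191), PIF and brassinosteroid elongation (11, 0.160), phosphate starvation (9, 0.641, 1 each way adjusted over the list alone) and meristem and leaf polarity (10, 0.987). The last has a median of 0.02 (−0.06 without pkl-1 2 to 0.09 without pkl-1 1) and a mean of 0.15 while its test points down. The anther and pollen list had 2 tested members, LAP6 and QRT3, and neither was called in any mutant. Genes named for pkl-1 that lost their call without 1 library were as follows. PKR1 lost it without WT 1, 2 or 3 or pkl-1 1, 2 or 3 (up to 0.127), and RING1B without WT 1, WT 3, pkl-1 1 or pkl-1 3 (0.146). ERD10 (0.106), RD29A (0.284) and JAZ1 (0.182) lost it without WT 3 or any pkl-1 library, and RAB18 without WT 3, pkl-1 2 or pkl-1 3 (0.125). AGL24 lost it without WT 1, WT 2, pkl-1 1 or pkl-1 2 (0.102), FT (0.115) and PDF1.2A (0.170) without WT 1, WT 3 or any pkl-1 library, and MYC2 without WT 2, WT 3 or any pkl-1 library (0.179). GA2OX2 (0.0875) and JAZ5 (0.170) lost it without WT 2, WT 3, pkl-1 2 or pkl-1 3, SEN1 without pkl-1 3 (0.0519) and PYK10 without WT 1 or WT 3 (0.0666).

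In the libraries labelled clf-28, 3 of 11 tested floral identity genes rose in shoots, a list called by camera with its preset correlation (adjusted p = 2.24e-08) and not with an estimated one (0.0828). SEP3 went from 0.343 ± 0.0707 to 26.4 ± 7.29 CPM, 76.0-fold (log2 fold change 6.25 ± 0.56 SE, n = 3, adjusted p = 3.65e-05). AG went from 0.403 ± 0.272 to 26.7 ± 1.98 CPM, 64.2-fold (SE 0.62 on the log2 scale, adjusted p = 1.04e-04). FT rose from 0.920 ± 0.243 to 8.10 CPM, 8.82-fold (3.14 ± 0.48, 0.00243). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 187 genes were higher and 251 lower than in WT, 438 in all. Without 1 library the total was 248 (WT 2), 180 (WT 3), 234 (clf-28 1), 191 (clf-28 2) and 169 (clf-28 3), and DESeq2 called 830. The authors' deposited table lists 304 genes higher and 418 lower.

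AT4G13577 had 3 reads in WT and 728 in clf-28, a ratio of 246 (95% counting interval 84.0 to 1197; adjusted p = 1.48e-05). All 3 reads lie in WT 2, and against the other WT libraries the gene was at least 153-fold higher. AT1G75945, with no read in WT, was at least 52.4-fold higher (0.00218; 32.6-fold without WT 2). FKF1 rose 41.9-fold (0.00617), the lipid transfer protein gene LTP4 30.1-fold (5.62e-04), AT4G33980 26.5-fold (0.00952) and COR27 47.7-fold (0.0338). As in pkl-1, it was not tested whether another collection time of WT moved FKF1, AT4G33980 and COR27. The largest falls were MRD1 (62.0-fold, 6.51e-04), the receptor-like kinase gene CRK4 (29.5-fold, 6.90e-04), AT3G16670 (137 ± 15.8 to 7.04 CPM, 19.5-fold, 3.94e-07) and CYP94B1, an enzyme of jasmonate turnover (19.1-fold, 0.00160). RAP2.6 (16.0-fold, 0.00931), PR2 (13.1-fold, 0.00215), MYB47 (12.5-fold, 0.00512) and RLP23 (12.4-fold, 1.60e-04) followed. MRD1 overlaps HEI10. COR27 lost its call without any 1 of the 6 libraries (WT 1 to 3, clf-28 1 to 3; up to 0.139), AT4G33980 without WT 3 (0.0560), and RAP2.6 without WT 3, clf-28 1 or clf-28 3 (0.0704). Without WT 3, CYP94B1 was 9.60-fold and RAP2.6 7.74-fold lower and FKF1 84.8-fold higher. AT4G33980 was 54.0-fold higher without WT 2.

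Of 11 floral MADS-box and floral identity genes, 3 rose in clf-28 and none fell (5 higher adjusted over the list alone). The third was SHP2, a carpel gene (11.5-fold, 0.0402). The list was called higher (camera adjusted p = 2.24e-08, median 0.38; adjusted p = 0.0828 with an estimated correlation). In the flowering time list 4 of 17 rose (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0932). Besides FT these were AGL19 (38.7-fold, 0.0189), a promoter of flowering, FLC (6.88-fold, 0.0394), a repressor of flowering, and SPL4 (2.49-fold, 0.0478). STM was not called (0.15 ± 0.43, 0.928). In the circadian clock list 4 of 11 rose (6 higher and 2 lower adjusted over the list alone; 3.23e-04, adjusted p = 0.0828 with an estimated correlation). LUX rose 2.96-fold (0.00129), GI 3.67-fold (0.00294), TOC1 3.64-fold (0.0286) and ELF4 from 3 to 244 reads, a ratio of 82.6 (95% counting interval 27.9 to 403; 0.0142; ratio 173 without WT 3). WT collected at another time of day than clf-28, raised below, may explain these clock values, and an effect of the mutation stays open. SHP2 (up to 0.180), FLC (0.150) and TOC1 (0.128) lost their call without any 1 of the 6 libraries (WT 1 to 3, clf-28 1 to 3), AGL19 without WT 1, WT 2, clf-28 1 or clf-28 2 (0.0843), SPL4 without WT 2, WT 3 or any clf-28 library (0.168), and ELF4 when WT 1, WT 2 or WT 3 was left out (0.0656). AGL19 was 101-fold higher without WT 3, and the median of the floral list, 0.38, was 1.29 without WT 1 and 0.77 without clf-28 1. FLC overlaps AT5G01675, and SPL4 overlaps MIR156i.

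Salicylic acid defence genes were called lower as a list in clf-28 (1.58e-05, adjusted p = 0.254 with an estimated correlation), with a median of −0.57, and −0.36 without clf-28 2. Of 21 members 4 fell (1 higher and 8 lower adjusted over the list alone). Besides PR2 these were WRKY70 (2.77-fold, adjusted p = 0.00294), PBS3 (2.78-fold, 0.0397) and PR5 (2.70-fold, 0.0429). Of 12 jasmonate response genes 2 fell (7 adjusted over the list alone; 6.28e-04, adjusted p = 0.375 with an estimated correlation), the defensin gene PDF1.2A (4.34-fold, 0.00859) and AOS, an enzyme of jasmonate synthesis (2.61-fold, 0.0218). The PIF and brassinosteroid elongation list was called lower (6.28e-04; adjusted p = 0.269 with an estimated correlation) with no called member of 11 over all genes and 4 lower adjusted over the list alone. Of 12 cold and dehydration genes, ERD10 (2.52-fold) and RD29A (3.33-fold) fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.417). Flavonoid and anthocyanin genes were called higher as a list (0.0124; adjusted p = 0.446 with an estimated correlation), and so was phosphate starvation (0.0439; adjusted p = 0.428 with an estimated correlation and 0.0533 with replicate number as a block). Neither list has a called member over all genes, and adjusted over the list alone they have 0 and 1 higher. PBS3 (up to 0.176) and PR5 (0.192) lost their call without WT 1, WT 2 or any clf-28 library. AOS lost it without WT 2, WT 3, clf-28 2 or clf-28 3 (0.128), PDF1.2A without clf-28 2 or clf-28 3 (0.0549), and ERD10 (0.107) and RD29A (0.150) without WT 3 or any clf-28 library. Without WT 3, ERD10 was 1.66-fold and RD29A 1.68-fold lower and the median of their list was 0.03 against −0.64, and −0.42 without clf-28 3. Without WT 2, PDF1.2A was 2.53-fold lower and the median of the flavonoid list 1.26 against 0.50, and without WT 1 that median was 0.26.

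No member was called over all genes in the remaining lists in clf-28. They were Polycomb machinery (20 tested, camera adjusted p = 0.724), SWR1, H2A.Z and CHD remodelers (10, 0.724), gibberellin (17, 0.587), heat shock (8, 0.524), photosynthesis (16, 0.278) and root markers (3, 0.397). Leaf senescence (6, 0.641) had 1 member higher adjusted over the list alone, and meristem and leaf polarity (10, 0.313) had 2. Embryo and seed storage (5, 0.837) has a median of −0.38, or 0 with SESA1, at or under the floor in both groups, taken as unchanged. The median of −0.38 ranged from −0.71 without WT 1 to 1.01 without WT 2, and was 0.08 without clf-28 3.

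In pie1-5, ATSDI1, LSU2, LSU3 and LSU1 were among the 8 largest rises by the naming rule, at 55.8-, 34.8-, 32.0- and 21.7-fold (log2 fold changes 5.80 ± 0.69, 5.12 ± 0.66, 5.00 ± 0.54 and 4.44 ± 0.50 SE, n = 3). These genes are known to respond to sulfur deficiency, and no list of such genes was tested. Their adjusted p-values were 2.53e-04, 4.54e-04, 1.12e-04 and 1.71e-04, and pie1-5 1 carries much of the folds (LSU2 at 177, 25.2 and 27.8 CPM in pie1-5 1, 2 and 3, against 2.17 ± 0.832 in WT). Without pie1-5 1 their log2 fold changes were 4.49, 3.59, 4.15 and 3.75, all called. Of the FLC clade of flowering repressors, MAF5 fell 31.5-fold (−4.98 ± 0.85, 0.00280; 20.2-fold without WT 1 and 68.0-fold without pie1-5 3) and MAF4 21.3-fold (−4.42 ± 0.72, 0.00193). WRKY70 rose from 16.6 ± 1.72 to 59.5 ± 24.1 CPM, 3.59-fold (1.84 ± 0.23, 3.09e-04). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 775 genes were higher and 725 lower than in WT, 1500 in all. Without 1 library the total was 866 (WT 1), 917 (WT 2) and 749 (WT 3), and it was 2011 without pie1-5 1. A fit of these 2 genotypes alone called 513, and the authors' deposited table lists 1064 genes higher and 918 lower.

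The largest falls in pie1-5 were AT4G15096 (9.46 ± 2.29 to 0.130 ± 0.0334 CPM, 70.9-fold, adjusted p = 4.41e-08), MAP1B (52.1-fold, 2.63e-05) and the genes AT2G40955 (50.4-fold, 5.80e-08) and AT2G40960 (42.0-fold, 2.19e-07). QQS, an orphan gene tied to starch content (20.9-fold, 0.00280), RAP2.6 (19.9-fold, 0.00305) and AT5G05060 (11.7-fold, 4.34e-05) also fell. AT1G75945 was at least 178-fold higher than the floor in WT (2.14e-04; 110.5-fold without WT 2). AT5G26220 rose 17.8-fold (0.00446), AT3G53980 14.4-fold (5.09e-04) and AT2G27420 43.8-fold (15.7 ± 25.9 CPM, 0.0220). The AT2G27420 call was lost without WT 1, WT 2, WT 3 or pie1-5 1 (up to 0.648), and its fold was 1.98 without pie1-5 1. AT5G26220 was 6.33-fold higher without pie1-5 1 and 28.5-fold without WT 3. QQS was 10.1-fold lower without WT 1, RAP2.6 9.70-fold without WT 3, MAP1B 80.8-fold without pie1-5 3 and AT5G05060 21.2-fold without pie1-5 2.

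Of 21 salicylic acid defence genes, 12 rose in pie1-5 and none fell (15 adjusted over the list alone; camera adjusted p = 4.29e-14, median 1.28, adjusted p = 0.0828 with an estimated correlation). Besides WRKY70 they included NIMIN1 (2 to 485 reads, ratio 226, 95% counting interval 62.2 to 1869; 5.28e-04; both reads in WT 3, at least 105-fold higher without it, ratio 140.3 without WT 2), WRKY53 (2.69-fold, 0.00149) and WRKY33 (2.96-fold, 0.00686). Of 13 flavonoid and anthocyanin genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; 4.24e-06, adjusted p = 0.244 with an estimated correlation). CHI (5.42-fold, 0.00862), FLS1 (6.76-fold, 0.0141) and CHS (3.10-fold, 0.0138) encode enzymes of the pathway, and MYBL2, which fell 2.44-fold (0.0308), encodes a repressor of it. Of 9 phosphate starvation genes 3 rose (8 adjusted over the list alone; 1.26e-05, adjusted p = 0.208 with an estimated correlation), PS2 (7.62-fold, 0.00841), ACP5 (6.13-fold, 0.00440) and SQD1 (1.66-fold, 0.0217). The heat shock list was called higher (0.00279; adjusted p = 0.288 with an estimated correlation) with MBF1C (2.86-fold, 0.00711) as 1 of 8 over all genes and 4 adjusted over the list alone. Root markers were called higher (0.00897; adjusted p = 0.125 with an estimated correlation), with PYK10 at 65.0 ± 7.75 against 27.4 ± 7.06 CPM (2.37-fold, 0.00149; 1 of 3 in both counts). Calls lost without 1 library were CHS (WT 1 or WT 3, up to 0.0649), FLS1 (WT 3, 0.0653), MYBL2 (WT 1, 2 or 3 or pie1-5 3, 0.0915) and SQD1 (WT 1, 2 or 3 or pie1-5 1, 0.0803). Much of the flavonoid and phosphate folds rests on pie1-5 1, where CHI stood at 36.2 CPM against 7.45 and 7.77 in the other libraries. Without it CHI was 2.41-, FLS1 2.20-, CHS 1.87-, ACP5 3.39- and PS2 4.11-fold higher, all called. The list medians were then 1.14 against 1.63 for flavonoid genes, 0.98 for phosphate starvation and 0.83 against 1.52 for heat shock, and without WT 2 that of the flavonoid list was 2.26. WRKY53 overlaps 3xHMG-box2, and MBF1C overlaps ALDH2C4 and MSH7.

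In the flowering time list 4 of 17 fell in pie1-5 (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.397). Besides MAF4 and MAF5 these were MAF3 (1.99-fold, adjusted p = 0.0228) and FLC (56 to 3 reads, ratio 20.1, 95% counting interval 6.52 to 100.2; 0.0162). All 3 reads lie in pie1-5 1, and FLC was at least 12.8-fold lower without it, with a ratio of 13.2 without pie1-5 2. FT was not called by edgeR (1.44 ± 0.47, 0.0768; DESeq2 0.0368). The floral MADS-box and floral identity list was called higher (0.0457; adjusted p = 0.359 with an estimated correlation). SEP3 (3.33 ± 0.55 on the log2 scale, 3.48 ± 2.31 CPM, 0.00214) and AP3 (15.1-fold, 0.0316) rose and AGL24 fell (2.97-fold, 0.0109), 3 of 11, with 5 higher and 1 lower adjusted over the list alone. AG (0.77 ± 0.66, 0.550) and STM (0.20 ± 0.43, 0.833) were not called. In the meristem and leaf polarity list (camera adjusted p = 0.137) KNAT1 (2.19-fold, 0.00884) and KNAT6 (2.47-fold, 0.0461) rose, 2 of 10 (4 adjusted over the list alone). The circadian clock list was called higher (0.0457; adjusted p = 0.208 with an estimated correlation and 0.109 with replicate number as a block), with 3 of 11 higher (5 higher and 1 lower adjusted over the list alone). LUX rose 2.44-fold (0.00252), GI 2.93-fold (0.00513) and ELF4 from 3 to 171 reads, a ratio of 53.1 (95% counting interval 17.9 to 260; 0.0130), which was 111 without WT 3, 83.3 without pie1-5 1 and 34.0 without pie1-5 2. The ELF4 rise is absent from pie1-5 1, which had no read, against 3.15 and 2.45 CPM in the other libraries. LUX (10.6 against 19.7 and 16.7 CPM) and GI (7.00 against 17.0 and 19.7 CPM) were also lowest in pie1-5 1. The median of the clock list was 1.31, and 0.86 without pie1-5 1. A difference in collection time, raised below, cannot be told apart from an effect of pie1-5 on these clock genes. Calls lost without 1 library were MAF3 (WT 1, 2 or 3 or pie1-5 2, up to 0.0797), FLC (WT 2, pie1-5 2 or pie1-5 3, 0.0524), AP3 (WT 1, WT 3, pie1-5 2 or pie1-5 3, 0.125, with 9.53-fold without pie1-5 2 and 48.2-fold without WT 2), KNAT6 (WT 1, WT 2 or any pie1-5 library, 0.153) and ELF4 (WT 1 or WT 2, 0.0540).

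Among chromatin genes in pie1-5, the SWR1 subunit genes SWC6 (3.25-fold, adjusted p = 0.0378) and SWC2 (1.88-fold, 0.0468) fell, 2 of 10 in both counts (camera adjusted p = 0.123). VAL1, a repressor that acts with Polycomb, fell 1.85-fold (0.00686), while JMJ30 (5.52-fold, 0.0207) and RING1B (2.33-fold, 0.0290) rose, 3 of 20 Polycomb genes (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.319). The photosynthesis list was called lower (6.28e-04; adjusted p = 0.269 with an estimated correlation), with LHCA4 (1.60-fold, 0.0318) as 1 of 16 and 7 lower adjusted over the list alone. The jasmonate response list had 2 higher, THI2.1 (26.4-fold, 0.0101) and PDF1.2A (2.49-fold, 0.0349), and 3 lower, among them AOS (3.15-fold, 0.00392) and MYC2 (2.13-fold, 0.0126). Adjusted over the list alone they were 3 and 3 (camera adjusted p = 0.659), and the median (−0.35) and test point down while the mean (0.28) is positive. That median was 0.02 without WT 3, −0.04 without pie1-5 1 and −0.67 without WT 1. The THI2.1 rise is absent from pie1-5 1 (0.529 CPM against 20.3 and 14.4 in pie1-5 2 and 3, and 0.675, 0.556 and 0.0439 in WT). Cold and dehydration had RD29B (9.71-fold, 0.0159) and COR15B (5.06-fold, 0.0368) higher and COR47 (2.59-fold, 0.0232) lower of 12 (2 and 2 adjusted over the list alone, camera adjusted p = 0.597). The COR15B rise is absent from pie1-5 1 too (2.86 CPM against 35.5 and 36.0, and 2.21, 3.30 and 9.32 in WT). SEN1 fell 4.88-fold (0.0124; 1 of 6 senescence genes in both counts, camera adjusted p = 0.901), a list with a median of 0.24 (0.07 without pie1-5 1) and a mean of 0.02 whose test points down. Gibberellin (17, camera adjusted p = 0.319, 1 higher and 4 lower adjusted over the list alone), embryo and seed storage (5, 0.102) and PIF and brassinosteroid elongation (11, 0.479) had no called member over all genes. Calls lost without 1 library were SWC6 (WT 1, WT 2 or any pie1-5 library, up to 0.133), SWC2 (WT 1, WT 3 or any pie1-5 library, 0.189), JMJ30 (WT 1, WT 3 or pie1-5 3, 0.104) and RING1B (WT 1, WT 3, pie1-5 2 or pie1-5 3, 0.105). Others were LHCA4 (WT 1, 2 or 3 or pie1-5 1 or 3, 0.114), PDF1.2A (WT 1, WT 3 or pie1-5 3, 0.133), MYC2 (WT 3, 0.0688), RD29B (WT 1 or WT 3, 0.0657), COR15B (WT 1, WT 2, pie1-5 2 or pie1-5 3, 0.133) and COR47 (WT 3, 0.143). Without WT 3, COR47 was 1.71-fold lower and COR15B 8.96-fold higher. JMJ30 was 3.47-fold higher without pie1-5 3, and without pie1-5 2 THI2.1 was 16.9-fold higher and SEN1 7.62-fold lower. PDF1.2A was 4.26-fold higher without WT 2. The embryo list median, 1.99, was 1.40 without pie1-5 1. RING1B overlaps TPX2, and LHCA4 overlaps ATSMC2.

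**Figure D2:**
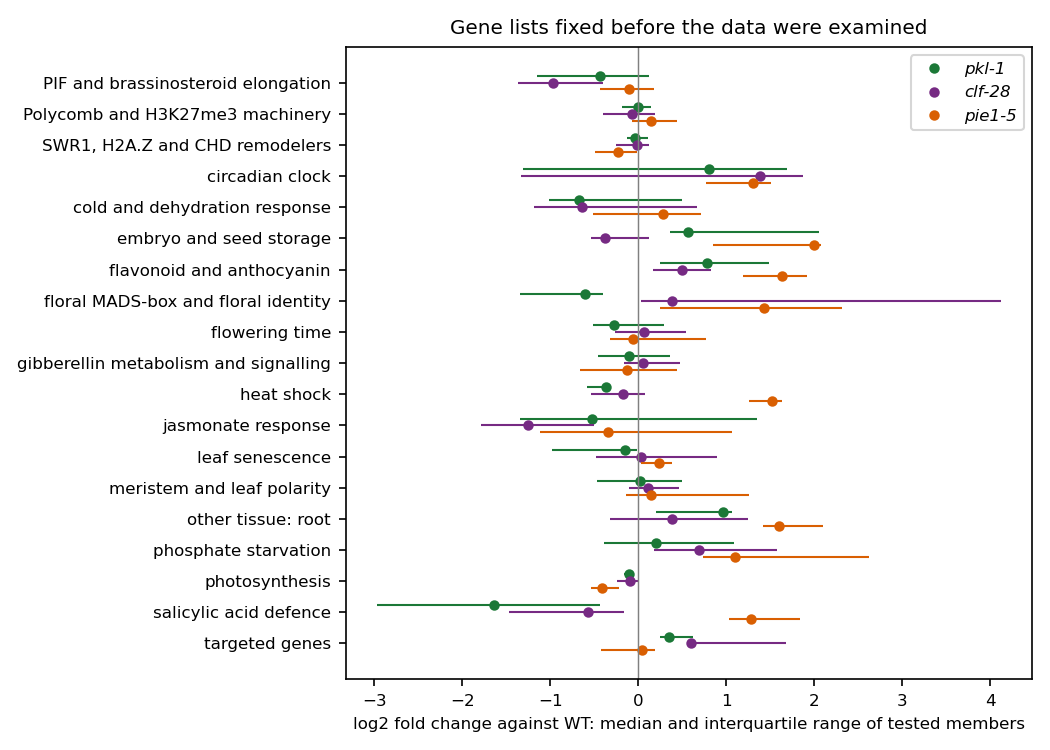
Median (point) and interquartile range (bar) of the log2 fold changes of the tested members of each gene list, for each mutant against WT. The salicylic acid defence list lies at −1.64 in pkl-1, −0.57 in clf-28 (−0.36 without clf-28 2) and 1.28 in pie1-5.

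To see which genes were called in several mutants, the calls were compared. In all 3 mutants 41 genes were higher and 29 lower, and 25 were called in all 3 with mixed signs. HCAR, an enzyme of chlorophyll turnover, was 3.12-, 3.28- and 3.29-fold higher in pkl-1, clf-28 and pie1-5 (adjusted p = 4.60e-05, 7.25e-05 and 4.34e-05). THIC, an enzyme of thiamine synthesis, was 2.60-, 3.03- and 2.45-fold higher, and CYP705A19 4.07-, 3.16- and 2.41-fold higher. MC2, a metacaspase gene, was 13.9-, 7.46- and 4.18-fold lower (6.70e-06, 1.04e-04 and 6.37e-04). AT3G22060 was 7.12-, 3.14- and 3.33-fold lower, AT5G59080 2.73-, 2.87- and 3.00-fold, CKX4, an enzyme that degrades cytokinin, 2.26-, 2.51- and 2.59-fold, and AT5G56980 4.49-, 3.72- and 2.80-fold. AT1G75945 and LUX, given above, were the others named among those higher in all 3. THIC overlaps AT2G29628.

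Between pairs, pkl-1 and clf-28 shared 190 genes called in the same direction (67 higher and 123 lower, 2.71 and 6.48 from independent lists) and 8 in opposite directions. The pair pkl-1 and pie1-5 shared 182 (95 and 87, 11.2 and 18.7) and 47 opposite, and clf-28 and pie1-5 shared 135 (69 and 66, 7.11 and 8.93) and 37 opposite. Unchanged groups simulated against shared WT libraries shared at most 1 gene in 20 simulations. With no gene changed there, hardly any could be called, so this gives no chance value for the counts above. The log2 fold changes of these pairs correlated across genes at 0.570, 0.339 and 0.398, against simulated values of 0.502, 0.503 and 0.505. Their covariances were 0.402, 0.276 and 0.297 against simulated values of 0.104, 0.104 and 0.105. Part of these overlaps may come from the shared WT libraries. WT collected at another time of day than pkl-1 and clf-28, raised below for clock genes, could also add shared calls, which was not tested. The counts of 190, 182 and 135 were 82, 70 and 46 without WT 3, and without WT 2 the first and the last were 123 and 74. Set against each other, pkl-1 and pie1-5 differed in 2242 genes (964 higher and 1278 lower in pkl-1), clf-28 and pie1-5 in 1784 (740 higher and 1044 lower in clf-28), and pkl-1 and clf-28 in 556 (253 higher and 303 lower in pkl-1). The first was 1412 without pkl-1 1 and 1288 without pkl-1 3. The second was 1037, 1142 and 888 without clf-28 1, 2 and 3. The third was 209, 298 and 314 without pkl-1 1, 2 and 3, and 223, 341 and 208 without clf-28 1, 2 and 3.

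For H3K27me3, a mark of Polycomb silencing, most regions were lower in pkl-1 in RPM, 92.8% of them in both replicates. These tests set 2 mutant libraries against 1 set of WT counts, treated as 1 library whose spread is assumed to equal theirs. A deviation of those WT counts would be counted as a change in the mutant. The region over AG (chromosome 4, 10378601 to 10389000) fell by 1.16 ± 0.16 SE on the log2 scale (2 libraries against 1 WT library, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.66e-10). Regions over STM (−1.09 ± 0.14, 6.88e-12), SEP3 (−0.98 ± 0.18, 1.91e-06), LEC1 (−0.94 ± 0.22, 1.5e-04), FT (−0.92 ± 0.25, 0.00144) and FLC (−0.86 ± 0.16, 7.50e-07) also fell. Of 5337 matched regions 2713 fell and 11 rose. The regions that fell cover 5124 of the 7650 genes in matched regions, among them 14 of 15 covered floral genes, 12 of 12 meristem genes, 11 of 11 root markers and 14 of 16 embryo and seed storage genes. Further lists were flowering time with 8 of 10, gibberellin 5 of 5, jasmonate 5 of 5, phosphate starvation 4 of 4, salicylic acid defence 5 of 8 and flavonoid 4 of 7. The remaining covered lists were PIF and brassinosteroid elongation with 5 of 8, cold and dehydration 3 of 3, Polycomb 2 of 3, SWR1 2 of 2, anther and pollen 2 of 4 and senescence 1 of 2. The largest falls lay at chromosome 1, 13603001 to 13605800 (no gene, −2.11 ± 0.43, 1.20e-05), chromosome 5, 14760001 to 14762000 (AT5G37280, −2.10 ± 0.41, 5.24e-06) and chromosome 3, 19879201 to 19880000 (no gene, −2.06 ± 0.53, 6.38e-04). The largest rises lay at chromosome 1, 1058401 to 1059200 (2.12 ± 0.56, 8.23e-04), chromosome 2, 19697601 to 19698200 (2.07 ± 0.29, 1.14e-10) and chromosome 5, 20629801 to 20630800 (1.96 ± 0.57, 0.00228), none over a gene. These falls are relative to all reads of a library. With TMM over the matched regions 9 rose and 0 fell (281 higher and 112 lower at an unadjusted p under 0.05), and the 6 regions over named genes lay between −0.36 and −0.06 with adjusted p from 0.680 to 0.962. By the deposited FDR of a single replicate 5185 regions differed without replicate 1 and 5027 without replicate 2.

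In clf-28 the H3K27me3 regions over floral genes had the lowest ratios among the named genes. The region over AG had log2 ratios of −2.69 and −3.17 in the 2 libraries (57.0 RPM in replicate 2; adjusted p = 0.932 by edgeR's quasi-likelihood test, with TMM −1.86 and 0.0570). The ratios were −1.59 and −3.20 over SEP3, −1.29 and −2.74 over STM, −0.96 and −2.20 over FT and −0.31 and −1.60 over LEC1 (0.08 with TMM). Over FLC it was −1.70 in replicate 2, with 180.5 RPM in replicate 1 against 511 RPM in WT. Of 5441 regions 0 passed the threshold (2 higher and 1 lower at an unadjusted p under 0.05; with TMM 43 higher and 0 lower). The replicates differed in level, with median log2 ratios of −0.40 and −1.81, and in the simulation for this comparison no 4-fold change was recovered. Of the regions, 75% were lower in both replicates, and 1984 were at least 1.5-fold lower in both. By gene list, lower in both replicates were 14 of 15 floral genes, 10 of 10 flowering time genes, 12 of 13 meristem genes, 10 of 11 root markers and 10 of 16 embryo and seed storage genes. The same held for PIF and brassinosteroid elongation in 7 of 8, salicylic acid defence 6 of 8, flavonoid 5 of 7, jasmonate 5 of 5, gibberellin 3 of 5, phosphate starvation 3 of 4, Polycomb 3 of 3, SWR1 2 of 2, senescence 2 of 2, anther and pollen 2 of 4 and cold and dehydration 1 of 3, none of them called. By the deposited FDR of a single replicate 5275 regions differed without replicate 1 and 4538 without replicate 2.

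In pie1-5 the ratios of H3K27me3 over the same genes were −0.36 and −0.40 (AG), −0.71 and −0.29 (SEP3), −0.44 and −0.22 (FLC), −0.40 and −0.34 (STM), −0.07 and −0.53 (FT) and −0.48 and −0.27 (LEC1), all with adjusted p = 0.996. With TMM the values over FLC (0.02) and FT (0.07) were positive. Of 5180 regions 1 rose and 0 fell by edgeR's quasi-likelihood test (12 higher and 86 lower at an unadjusted p under 0.05; with TMM 3 higher and 0 lower). The region that rose spans chromosome 2, 3259601 to 3509800, with 171 genes (0.98 ± 0.09, 1.51e-24; 2 libraries against 1 WT library whose spread is assumed to equal theirs), next to the centromere, where the chromosome carries inserted mitochondrial DNA. Median log2 ratios over the matched regions were −0.81 in pkl-1 (replicates −0.69 and −0.92), −1.11 in clf-28 and −0.36 in pie1-5 (−0.45 and −0.20). The share of reads inside regions was 40.0% and 36.2% in pkl-1, 46.8% and 53.3% in clf-28 and 55.9% and 58.0% in pie1-5, against 65.2% to 70.3% in WT. With TMM the medians were 0.01, −0.04 and 0.01. Across regions, the log2 ratios of the replicates correlated at 0.548 in pkl-1, 0.563 in clf-28 and −0.03 in pie1-5. By the deposited FDR of a single replicate of pie1-5 4315 regions differed without replicate 1 and 4753 without replicate 2.

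H2A.Z, the histone variant placed by SWR1, was lower in RPM across most regions of pie1-5. The median log2 ratio over 14570 matched regions was −0.78 (−1.15 in replicate 1 and −0.41 in replicate 2), 93.2% of regions were lower in both replicates and 3095 were at least 1.5-fold lower in both. The share of reads inside regions was 55.6% in replicate 1 against 64.3% in WT, and 49.6% in replicate 2 against 64.2%. The replicate with the lower median thus had the higher share. By gene list, 13 of 13 covered salicylic acid defence genes, 15 of 15 embryo and seed storage genes, 12 of 12 root markers and 9 of 9 heat shock genes were lower in both replicates. So were 9 of 9 PIF and brassinosteroid, 9 of 9 meristem, 8 of 8 cold and dehydration, 8 of 8 phosphate starvation, 6 of 6 anther and pollen, 5 of 5 flowering time and 4 of 4 jasmonate genes. The same held for 3 of 3 floral, 3 of 3 SWR1, 3 of 3 senescence, 2 of 2 Polycomb and 1 of 1 clock genes, but for 10 of 11 flavonoid, 4 of 6 gibberellin and 1 of 2 photosynthesis genes. None of these regions passed edgeR's quasi-likelihood test with replicate as a block, in which 0 regions fell and 3 rose (463 lower and 4 higher at an unadjusted p under 0.05; with TMM 69 higher and 5 lower and a median of 0.02). The rises lay at chromosome 4, 5268201 to 5268400 (3.18 ± 0.65, adjusted p = 0.0114), chromosome 5, 11765401 to 11766000 (AT5G31909, 3.15 ± 0.66, 0.0114) and chromosome 2, 3417201 to 3509800 (66 genes, 2.48 ± 0.56, 0.0421). At an adjusted p below 0.01, or with an overlap of at least 80% of the longer region, 0 regions were called. By the deposited FDR of a single replicate 12983 regions differed without replicate 1 and 14502 without replicate 2.

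In pkl-1 the median H2A.Z ratio was 0.00 over 9861 matched regions (0.01 and −0.02), and 73 regions rose and 56 fell (with TMM 122 and 86). The largest falls lay at chromosome 4, 6591201 to 6594400, over AT4G10690 and AT4G10695 (−2.12 ± 0.09 SE, n = 2, adjusted p = 1.62e-11), chromosome 1, 7973801 to 7974600 (no gene, −1.23 ± 0.19, 0.00174) and chromosome 1, 23711401 to 23712000 (no gene, −1.20 ± 0.25, 0.0171). The largest rises lay at chromosome 4, 8959601 to 8960200 (no gene, 2.68 ± 0.25, 2.16e-06), chromosome 1, 17342001 to 17343600 (AT1G07347, 1.21 ± 0.17, 4.94e-04) and chromosome 5, 20592801 to 20594400 (AT5G50610, 1.14 ± 0.15, 1.79e-04). Regions over SEP3 (−0.11 ± 0.08, 0.565) and LEC1 (−0.04 ± 0.08, 0.861) were not called, and neither was LEC1 in clf-28 (−0.15 ± 0.23, 0.687) or pie1-5 (−0.75 ± 0.60, 0.410). Over LEC1 the ratios of the replicates were −0.41 and 0.11 in clf-28 and −1.31 and −0.20 in pie1-5, and with TMM the values were positive (0.13 and 0.06). Without the block 1 region was called. By the deposited FDR of a single replicate 4677 regions differed without replicate 1 and 4514 without replicate 2. In clf-28 the median was −0.28 (−0.42 and −0.14) over 14539 regions, and 4 regions rose and 6 fell (37 higher and 1773 lower at an unadjusted p under 0.05; with TMM 38 higher and 4 lower). The 3 largest rises by the naming rule were chromosome 2, 3388201 to 3408000 (11 genes, 2.53 ± 0.34, 1.48e-09), chromosome 5, 20597601 to 20599800 (AT5G00635, 1.08 ± 0.24, 0.0224) and chromosome 5, 20621601 to 20625400 (HSD1 and HSD7, 0.95 ± 0.23, 0.0469). The fourth, at chromosome 5, 11765801 to 11766000 (AT5G31909, 2.41 ± 0.30, 1.13e-11), had 70 reads in clf-28 and 49 in WT in replicate 2, below the minimum of the rule, and is named after its values were seen. The clf-28 rises over AT5G00635 and over HSD1 and HSD7 lie near 1 another and near rises in pkl-1. Those were H2A.Z over AT5G50610 (20592801 to 20594400) and H3K27me3 at 20629801 to 20630800. The cause was not tested, and input reads there were not analysed. The 3 largest falls were chromosome 1, 13353601 to 13354200 (−1.66 ± 0.30, 2.22e-04), chromosome 3, 21434001 to 21434400 (−1.64 ± 0.34, 0.00301) and chromosome 1, 26675201 to 26676000 (−1.55 ± 0.31, 0.00179), none of these 3 over a gene. Of the other 3 falls 1 covers genes, at chromosome 5, 22833801 to 22837800 (AT5G56368, AT5G56369 and AT5G56370, −0.98 ± 0.23, 0.0469; chosen after its values were seen). Without the block 0 regions were called in clf-28 by edgeR (13 higher and 1681 lower at an unadjusted p under 0.05), and by the deposited FDR of a single replicate 10094 regions differed without replicate 1 and 13275 without replicate 2.

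**Figure D3:**
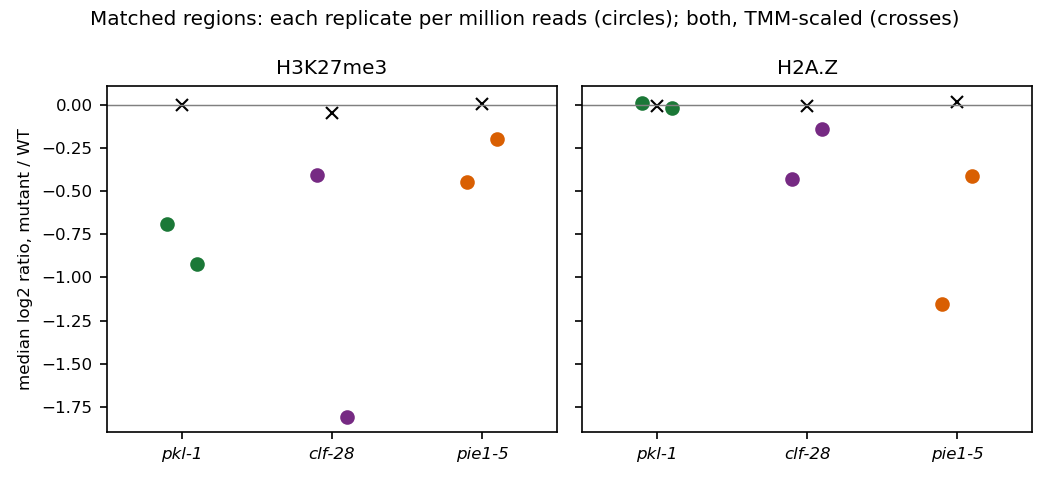
Median log2 ratio of mutant to WT over matched regions for H3K27me3 and H2A.Z, 1 circle per replicate on RPM and crosses for TMM over the matched regions. H3K27me3 in clf-28 lies at −0.40 and −1.81 and H2A.Z in pie1-5 at −1.15 and −0.41, while with TMM the medians lie between −0.04 and 0.02.

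To join the marks with expression, called genes were placed in the regions. In pkl-1, 24.4% of the 295 genes that rose and 24.5% of the 526 that fell lay in H3K27me3 regions, against 11.3% of tested genes (Fisher's exact test, adjusted p = 2.26e-10 and 1.33e-17). In clf-28 these were 31.0% and 33.9% against 11.4% (6.55e-13 and 1.37e-20), and in pie1-5 22.1% and 13.5% against 11.1% (1.53e-18 and 0.0441). H2A.Z regions held 48.1% of genes that rose and 37.8% of those that fell in pkl-1 against 24.8% of tested genes (7.49e-18 and 2.86e-11). In clf-28 they held 48.1% and 52.6% against 27% (8.39e-10 and 1.33e-17), and in pie1-5 47.7% and 23.3% against 26.0% (1.73e-38 and 0.0928). Genes are not independent replicates, and genes in 1 region count separately, so the Fisher p-values describe these libraries only. The background was not matched on expression level. The 1398 tested genes in H3K27me3 regions that fell in pkl-1 had a median log2 fold change of −0.06 and a mean of 0.04 in RNA (camera adjusted p = 0.955), with 47 called higher and 67 lower (75 and 90 adjusted over the list alone). Those regions were called against 1 WT library whose spread is assumed to equal that of the mutant libraries. As a set, the 25 tested genes in H2A.Z regions that fell in pkl-1 were called higher in RNA (median 0.48, camera adjusted p = 8.07e-07, and adjusted p = 0.00572 with an estimated correlation). Of them 4 were called higher and 2 lower (8 and 3 adjusted over the list alone). The H2A.Z regions that fell or rose in pkl-1 were called with replicate as a block, and without the block 1 region was called. The 49 tested genes in H2A.Z regions that rose in pkl-1 were called lower as a set (median −0.62, camera adjusted p = 8.81e-07, and adjusted p = 0.0179 with an estimated correlation), with 6 called lower and none higher (12 and none adjusted over the list alone). By the deposited FDR with a 1.5-fold rise in both replicates, 7 tested genes were not called (median −0.01, camera adjusted p = 0.0940, and 0.201 with an estimated correlation). In H2A.Z regions that rose in pie1-5, 47 tested genes were called higher (median 0.45, camera adjusted p = 2.36e-05, and 0.110 with an estimated correlation). Of the 67 genes in those regions, tested or not, 66 lie in 1 region, at chromosome 2, 3417201 to 3509800. They therefore stand for hardly more than 1 region. It lies in the stretch with inserted mitochondrial DNA, and whether reads there come from mitochondria was not tested. The 5 tested genes in H2A.Z regions that rose in clf-28 were not called (median −0.34, camera adjusted p = 0.760). Of 5302 genes covered by both marks in pkl-1, 21 lay in regions that fell for both, against 17.8 from independent lists (odds ratio 1.81, Fisher's exact p = 0.226). No gene lay in H3K27me3 regions that fell by edgeR's test in both mutants of a pair, since 0 regions fell in clf-28 (1 lower at an unadjusted p under 0.05, 0 with TMM) and in pie1-5 (86 lower, 0 with TMM).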

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

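Definitions from the deposited FDR with a 1.5-fold difference, and the filter and size-factor settings for shared and between-mutant counts, were chosen after the data were seen; the other settings were fixed before. Of 152 called pairs of a named gene and a mutant, 98 stayed past the threshold whichever library was left out, and 152 kept their sign. The threshold was kept by 151 of 152 with RLE size factors, 152 of 152 without a filter, 125 of 148 with only the 2 genotypes compared, and 148 of 149 with DESeq2. No called pair reversed its sign in any of these settings. Uncalled values that changed sign were PKL in pie1-5 (−0.13 without pie1-5 3 to 0.20 without pie1-5 2), CLF in pkl-1 (−0.0676 without WT 3 to 0.58 without WT 2), and STM in clf-28 (−0.10 to 0.53) and pie1-5 (−0.0596 to 0.58), each without WT 3 and WT 2. The cause was not tested.

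Gene counts for pkl-1, clf-28 and pie1-5 were 1763, 1174 and 2358 without a filter on low counts, and 1470, 940 and 513 with only the 2 genotypes compared. DESeq2 gave 1401 and 830 in pkl-1 and clf-28. Without a filter, pkl-1 and clf-28 differed in 1332 genes and clf-28 and pie1-5 in 2747. Shared counts without a filter were 507 (pkl-1 and pie1-5), 598 (pkl-1 and clf-28) and 408 (clf-28 and pie1-5). Leaving out 1 library gave 412 to 596 genes in pkl-1, 169 to 332 in clf-28 and 749 to 2011 in pie1-5. Between mutants it gave 1288 to 2347 (pkl-1 and pie1-5), 208 to 341 (pkl-1 and clf-28) and 888 to 1957 (clf-28 and pie1-5). Shared counts ranged over 70 to 128, 82 to 160 and 46 to 92 in the order above. Fewer libraries remain in these fits, and why other settings moved the counts was not tested.

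With replicate number as a block, 812, 385 and 1509 genes were called in pkl-1, clf-28 and pie1-5, and 139 of 152 named pairs kept the threshold. In deviations from genotype means, RNA libraries of the same number correlated between −0.05 and 0.125 and those of different numbers between −0.099 and 0.076. The 0.125 was between clf-28 3 and pie1-5 3, so a weak pairing by number cannot be excluded. Of 57 tests of a list in a mutant, 21 passed with the preset correlation, 19 with the block and 0 with an estimated correlation. The calls that ended with the block were the clock list in pie1-5 (adjusted p = 0.109) and phosphate starvation in clf-28 (0.0533).

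H3K27me3 counts for pkl-1, clf-28 and pie1-5 were 9, 43 and 3 regions with TMM, and 4803, 4006 and 2858 by the deposited FDR in both replicates. An adjusted p below 0.01 left 1740 in pkl-1. A single replicate by the deposited FDR gave 5027 to 5185, 4538 to 5275 and 4315 to 4753. For H2A.Z the counts were 208, 42 and 74 with TMM, 49, 5 and 0 at an adjusted p below 0.01, and 1682, 7367 and 12779 by the deposited FDR in both replicates. An overlap of 80% of the longer region gave 2 in clf-28 and 0 in pie1-5, and no block gave 1 in pkl-1 and 0 in clf-28. Single replicates gave 4514 to 4677, 10094 to 13275 and 12983 to 14502. Median log2 ratios with TMM were 0.00535, −0.0431 and 0.0110 for H3K27me3, and −0.00451 in clf-28 and 0.0217 in pie1-5 for H2A.Z, because TMM sets the bulk of regions to no change. From single replicates the medians ranged over −0.92 to −0.69, −1.81 to −0.40 and −0.45 to −0.20 for H3K27me3, and over −0.02 to 0.01, −0.42 to −0.14 and −1.15 to −0.41 for H2A.Z.

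For RNA of genes in H3K27me3 regions that fell in pkl-1, the camera p was 0.882 and with any overlap of 1 bp 0.989 with the direction reversed. In regions at least 1.5-fold lower in both replicates it was 0.993 in pkl-1 and with any overlap 0.750, again reversed. In clf-28 it was 0.0230, 0.0145 with any overlap and 0.123 with an estimated correlation, and in pie1-5 0.0801 and 0.0268 with any overlap, all toward higher RNA. Adjusted, the clf-28 values were 0.0527, 0.0378 and 0.217, and the pie1-5 values 0.140 and 0.0581. Genes lower for both marks numbered 2, 25 and 28 in pkl-1, clf-28 and pie1-5 with the deposited FDR and a 1.5-fold difference, and 3, 51 and 39 with any overlap, against 21, 0 and 0 by edgeR's test. Independent lists would share 2.48, 19.4 and 18.1. Genes with lower H3K27me3 in both mutants numbered 222 (pkl-1 and pie1-5), 2636 (pkl-1 and clf-28) and 73 (clf-28 and pie1-5), and 302, 2918 and 100 with any overlap, against 0 by edgeR's test. Independent lists would share 147, 2192 and 104 (odds ratios 14.7, 2.91 and 0.555), so the last pair shares fewer than that. All are divided by the same WT counts, which can themselves move these numbers. The pair pkl-1 and pie1-5 also holds 2 libraries with close profiles, pkl-1 replicate 1 and pie1-5 replicate 2 (0.888, taken up below). A label error there cannot be excluded, and it could move the 222. The cause was not tested. A test of RNA in H3K27me3 regions that fell could not be run in clf-28 and pie1-5, where edgeR called none of them lower (1 and 86 at an unadjusted p under 0.05, 0 with TMM), and the H3K27me3 fit with a block could not be fitted with 1 WT library. H3K27me3 in clf-28 has both the fewest reads (6.44 and 3.17 M) and replicates that differ in median (−0.40 and −1.81), and which of these limits its calls was not tested.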

Other observations

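All tests in this part were chosen after the results were seen. A stretch of chromosome 2 next to the centromere was higher in several ChIP libraries than in WT. For H3K27me3 its log2 ratio of summed RPM was 1.23 and 1.90 in pkl-1 (250.4 and 270.8 kb covered), 1.33 and 3.35 in clf-28 (270.6 and 270.8 kb) and 0.97 and 1.00 in pie1-5 (250.2 kb each). For H2A.Z it was 2.73 and 2.32 in clf-28 (250.2 and 106 kb) and 2.47 and 2.54 in pie1-5 (267.2 and 128.8 kb), while in pkl-1 only 0.2 kb was covered.

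Evening clock genes were higher than in WT in all 3 mutants, with median log2 fold changes of 1.60 in pkl-1, 1.86 in clf-28 and 1.29 in pie1-5 over 5 genes, and 3, 4 and 3 of them called, while the 4 morning genes had medians of −1.53, −1.71 and 1.44, none called. The evening rise is not shared by pie1-5 1, where TOC1 (4.36 CPM against 7.29 to 8.44 in WT), ELF3 (2.24 against 7.61 to 8.35) and ELF4 (0 CPM) were not above WT, and LUX and GI were above it (10.6 and 7.00 CPM), genes chosen after their values were seen. The 1.44 rests on pie1-5 1, where CCA1 stood at 44.1 CPM and LHY at 59.6 CPM against 1.53 and 1.36 and 0.573 and 1.16 CPM in pie1-5 2 and 3 (genes chosen after their values were seen), and without it the morning median in pie1-5 was −1.83. A single WT library is argued against, since without any 1 WT library the evening medians stayed at 0.940 times their value or more. WT collected at another time of day than pkl-1 and clf-28 may explain the opposite movement there (−1.53), and pie1-5 1 collected at another time than pie1-5 2 and 3 may explain its morning genes (−1.83 without it). For pie1-5, and so for 1 shift of WT against all 3 mutants, a shift cannot be told apart from a genotype effect, because 1.44 comes from 1 library, collection times are not given in the sources used here, and an effect of the mutations on the clock stays open, untested.

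H3K27me3 over floral genes in clf-28 lay low among 10000 matched random lists, at percentile 7.5 in replicate 1 and 0.06 in replicate 2. With the higher percentile at 7.5, an even rise of background reads in the clf-28 immunoprecipitations could account for the floral values in replicate 1, and a loss specific to floral genes stays open as the biological alternative. In pkl-1 the percentiles were 30.1 and 0.29, and in pie1-5 63.6 and 20.1.

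The H3K27me3 log2 ratios of pkl-1 replicate 1 correlated with those of pie1-5 replicate 2 at 0.888 across genes, above the pkl-1 pair (0.763) and the pie1-5 pair (0.124). Division by the same WT values is argued against, since without WT the correlation was 0.938, against 0.839 in the pkl-1 pair and 0.562 in the pie1-5 pair. In pie1-5 replicate 2, 58.0% of reads lay inside regions, beside 40.0% and 36.2% in the libraries labelled pkl-1. Only 2 pkl-1 libraries give the spread of that share, so a label error in either library of the pair cannot be excluded. A preparation shared by those libraries may be the cause and cannot be told apart, since the H2A.Z pair of the same numbers correlated at 0.641 and no preparation is given in the labels. Other libraries also grouped across genotypes. Without WT, the H2A.Z replicate 2 libraries correlated at 0.793 (pkl-1 and clf-28), 0.821 (pkl-1 and pie1-5) and 0.845 (clf-28 and pie1-5), above the pairs of 1 genotype (0.745, 0.597 and 0.521). The H3K27me3 log2 ratios of pkl-1 and clf-28 replicate 2 correlated at 0.823, above both their own pairs (0.763 and 0.657), but without WT at 0.741, below the pkl-1 pair. What these libraries share is not given in the labels, and no biological explanation was tested.

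With 10 splits of 6 libraries into groups of 3, the share of splits with as many genes cannot go under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes. The real counts were 821 (pkl-1), 438 (clf-28), 1500 (pie1-5), 2242 (pkl-1 against pie1-5), 556 (pkl-1 against clf-28) and 1784 (clf-28 against pie1-5). The highest of the other splits gave 12 in pie1-5 and 0 in the other 5 comparisons by edgeR's test.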
